A study of Homo sapiens with 16 samples.

How the data were processed

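The samples were 16 poly(A) RNA sequencing libraries from the NGP cell line, an established human neuroblastoma line. They formed 4 groups of 4: vehicle (DMSO) or 3 µM HCI-2509, each for 4 h or 24 h. Per the labels' protocols, poly(A) RNA was selected with oligo(dT) beads, libraries were made with a TruSeq RNA kit and sequenced as single reads. The submitters' processing notes name Novoalign 2.08.01, DESeq2 and the genome build hg19 without saying which step each served. The counting program, the annotation release and the strand setting are not given in the sources used here. The kit does not mark strand, so reads of overlapping and antisense genes cannot be told apart from the counts, and genes with near-identical copies are given as uncertain.

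The deposited tables, one per time point, hold whole-number read counts per gene and library, whose column totals differ as those of counts that are not normalized do. They also hold the authors' deposited log2 fold change and the authors' deposited adjusted p-value per gene. Of the genes past the authors' adjusted p of 0.05, 100.0% at 4 h and 98.6% at 24 h had the sign of treated over vehicle in the counts. There were 18378 genes at 4 h and 18380 at 24 h, and 17996 genes were in both tables. The lowest count total of a gene over the 8 libraries was 12 at 4 h and 15 at 24 h. A gene outside these tables was not analysed here, and library totals are sums over the listed genes. Each table had 23 gene names that had been turned into dates, which were restored from the Ensembl identifiers.

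Columns were assigned to samples by the sample titles. Total counts per library ranged from 13478695 to 21482214. The chi-square per degree of freedom between replicates of a group ranged from 1.54 to 8.38 over 24 pairs, so no pair was as close as sampling noise alone and each library counted as a replicate. The labels describe replicate wells and name no separate cultures, so p-values measure only the spread between these samples, which may be technical. Replicate numbers were checked for pairing by the correlation of deviations from the group means. At 24 h the correlations of same-numbered libraries were 0.423, 0.428, 0.393 and 0.253, and the numbers were taken to pair the samples there. This pairing comes from the data, since the labels state no shared batch. It is not established, since correlations as high occurred between libraries of different times and numbers. Vehicle 4 h replicate 3 had 0.57 with vehicle 24 h replicate 4, and vehicle 4 h replicate 4 had 0.477 with HCI-2509 24 h replicate 1.

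Each time point was fitted on its own 8 libraries with edgeR 4.0.16 in R 4.3.3: filterByExpr, TMM scaling, and the robust quasi-likelihood test, with Benjamini-Hochberg adjustment and a threshold of 0.05. A total of 16833 genes were tested at 4 h and 16822 at 24 h. A 2-fold change meant an absolute log2 fold change of at least 1. Expression levels are given as CPM, counts scaled to library size with TMM factors. The difference between times (24 h effect minus 4 h effect) was the interaction term of one edgeR fit of all 16 libraries, over 17408 genes. All adjusted p-values of single genes come from these edgeR tests unless the authors' deposited table is named. Standard errors (SE) of genes are the absolute log2 fold change divided by the square root of the quasi-likelihood F. The SE of a list median comes from the SD over list members. It takes the members as independent and does not measure the spread between libraries.

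A set of 31 gene lists with 985 entries was fixed before the data were examined, as were the tests, most other settings tried and the rule for naming genes. Of the entries, 118 were not matched to a listed gene, and 4 were matched through older symbols. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over all lists with at least 3 tested members. Genes were named by 3 parts of a rule. Part 1 took the 6 largest rises and the 6 largest falls at each time among genes past the threshold with a mean of at least 1 CPM and no overlap between groups. Part 2 always took certain genes, among them KDM1A, MDM2, CDKN1A and MYCN. Part 3 took up to 4 members of a described list with the largest absolute change among those past the threshold. Some genes that the rule took are not reported here.

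The other settings fixed at that point were DESeq2 1.42.0, DESeq2 size factors in the edgeR fit, no low-count filter, the replicate number as a block, leaving out each library in turn, an adjusted p under 0.01, the authors' deposited adjusted p, and all 16 libraries in one fit. For lists they were an estimated correlation, fry, a rank-based test, the block and leaving out each library. Total-count scaling, and a correction for GC content and transcript length, were chosen after seeing the data. The correction removed a smooth trend of each library in both properties through an offset, and it used gene properties from an annotation of another build without any coordinates. Of the genes tested at 24 h, 96.5% had values for both. 3 further lists were written after the values had been seen.

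The procedure was tested on simulated counts with a seeded set of changed genes per comparison. At 4 h, 58% of genes simulated at a fold of 1.25 and 96% at a fold of 2 were recovered, over 16793 genes, and 4% of the calls were false. At 24 h these shares were 74% and 98% over 17070 genes, with 2.7% false calls. For the difference between times they were 42% and 86% over 17365 genes, with 3.9% false calls. The simulation changed only a small set of genes, built on the vehicle libraries with the same dispersion for all genes. It held no pairing and no trend in GC content or length. In the real libraries 70.8% of genes changed at 24 h, so these shares may not carry over to them.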

Results

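HCI-2509 is a reversible inhibitor of the histone demethylase LSD1, the product of KDM1A. RNA was sequenced from NGP neuroblastoma cells given vehicle or 3 µM HCI-2509 for 4 h or 24 h, with 4 libraries in each of the 4 groups. The question named by the series was how the inhibitor changes gene expression, and in particular the genes of the p53 response. Total counts per library, for replicates 1 to 4 in turn, were 15084582, 15081080, 19994594 and 13478695 in vehicle at 4 h and 13694543, 21482214, 15580703 and 19243858 in HCI-2509 at 4 h. They were 16880254, 15859654, 20580775 and 17415964 in vehicle at 24 h and 16542777, 16725400, 15346423 and 15680737 in HCI-2509 at 24 h. The first principal component held 79.7% of the variance between libraries and the second held 9.0%. The 10 genes with the most counts took 6.06% ± 0.208 of the counts in HCI-2509 at 24 h and 4.17% ± 0.137 in vehicle at 24 h (SD, n = 4). ENO1, a glycolytic enzyme, was the gene with the most counts in every HCI-2509 library at 24 h, and EEF2 was in every other library.

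The first comparison asked which transcripts had changed after 4 h of treatment. Of the 6 largest rises that were named, PFKFB4 and P4HA1 were on the hypoxia and HIF list, and the other 4 were not. Being off this list does not place a gene outside the response to low oxygen. BHLHE40 (ENSG00000134107), a transcriptional repressor, went from 4.70 ± 0.812 to 90.4 ± 7.59 CPM, an 18.9-fold rise, and STC1, a secreted glycoprotein, went from 2.19 ± 0.478 to 35.8 ± 2.01 CPM, a 16.2-fold rise (mean ± SD, n = 4). NXPH4 rose 14.8-fold, the glycolytic regulator PFKFB4 from 4.22 ± 0.551 to 50.8 ± 2.12 CPM, and P4HA1, a subunit of collagen prolyl hydroxylase, 8.42-fold. The long noncoding RNA MIR210HG rose 13.4-fold from 0.137 CPM, which was 0 to 4 counts per vehicle library. Of 34 tested genes on the list of hypoxia and HIF targets, 33 rose and 0 fell (34 and 0 adjusted over the list alone), with a median log2 fold change of 1.52. The list differed from other genes by camera (adjusted p = 2.68e-281), and the adjusted p was 0.000135 with an estimated correlation. SLC2A1, a glucose transporter, rose by 3.01 ± 0.06 (log2 ± SE) and ADM, which encodes adrenomedullin, by 3.00 ± 0.22.

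Falls at 4 h were smaller. CHAC1, which degrades glutathione, changed by −1.39 ± 0.35 (log2 ± SE) and the small nucleolar RNA SNORD3A by −1.01 ± 0.27. For SNORD3A at 4 h, leaving out vehicle 4 h replicate 1 gave −0.72 and ended the call (adjusted p = 0.0569). Since the libraries were poly(A) selected, the reads of SNORD3A may not measure the mature RNA. The chaperone genes HSPA1B, HSPA2 and HSPA1A fell by 1.21 ± 0.08, 1.16 ± 0.11 and 1.08 ± 0.22 on the log2 scale, and CTD-2636A23.2 fell by 1.03 ± 0.07. HSPA1A and HSPA1B are near-identical copies, so the split of reads between them is uncertain. On the heat shock list, 12 of 19 genes fell and 0 rose (15 and 0 adjusted over the list alone). Its camera adjusted p was 5.55e-09, and the adjusted p was 0.196 with an estimated correlation.

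Cell division genes were lower at 4 h. On the G2/M and mitosis list, 55 of 61 genes fell and 0 rose (57 and 0 adjusted over the list alone), with a median log2 fold change of −0.34. CENPA, a centromeric histone, went from 49.8 ± 2.03 to 27.5 ± 2.48 CPM, and CKS2, a cyclin-dependent kinase subunit, from 115.3 ± 14.4 to 65.0 ± 5.63 CPM (SD, n = 4). On the list of G1/S and DNA replication, 32 of 49 genes fell and 1 rose (35 and 1 adjusted over the list alone), among them the replication clamp PCNA (−0.77 ± 0.07) and UHRF1 (−0.71 ± 0.06). Both lists passed camera (adjusted p = 3.85e-26 and 7.60e-14), and both had an adjusted p of 0.216 with an estimated correlation. For each of the 2 lists, 3 of the 35 splits of the 8 libraries into 4 and 4 gave a camera p as small as the real one. On the replication-dependent histone list, 6 of 25 genes fell and 1 rose (6 and 1 adjusted over the list alone; camera adjusted p = 0.0422). HIST1H3D changed by −1.40 ± 0.33 and HIST1H1B by −1.38 ± 0.32, and the adjusted p of the list was 0.595 with an estimated correlation. Transcripts of these histone genes mostly lack a poly(A) tail, and the libraries were poly(A) selected.

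Genes of sterol synthesis also fell at 4 h. On the list of cholesterol biosynthesis and SREBP2 targets, 16 of 25 genes fell and 1 rose (16 and 2 adjusted over the list alone). The camera adjusted p was 6.12e-12, and the adjusted p was 0.0258 with an estimated correlation. HMGCS1, which makes HMG-CoA, went from 297.8 ± 27.2 to 153.7 ± 6.47 CPM (SD, n = 4), and IDI1, INSIG1 and MSMO1 fell by 0.79 ± 0.07, 0.68 ± 0.05 and 0.66 ± 0.06 on the log2 scale. On the list of nuclear-encoded oxidative phosphorylation genes, 24 of 59 fell and 0 rose (24 and 0 adjusted over the list alone; camera adjusted p = 1.24e-06, and adjusted p = 0.0757 with an estimated correlation). CYCS, which encodes cytochrome c, changed by −0.52 ± 0.07 and NDUFS6, a complex I subunit, by −0.47 ± 0.06. On the ribosome biogenesis list, 17 of 38 genes fell and 1 rose (18 and 3 adjusted over the list alone; camera adjusted p = 6.14e-05, and adjusted p = 0.216 with an estimated correlation), with UTP15 at −0.49 ± 0.08 and RRS1 at −0.47 ± 0.06.

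3 further lists were higher by camera at 4 h. On the LSD1 and CoREST list, 8 of 21 genes rose and 1 fell (8 and 1 adjusted over the list alone; camera adjusted p = 0.000159, and adjusted p = 0.0447 with an estimated correlation). The corepressor genes RCOR2 and RCOR3 rose by 0.83 ± 0.06 and 0.62 ± 0.05. On the iron starvation list, 4 of 12 genes rose and 1 fell (4 and 1 adjusted over the list alone; camera adjusted p = 0.000152, and adjusted p = 0.0447 with an estimated correlation). TFRC, the transferrin receptor, went from 243.7 ± 23.9 to 826.1 ± 30.6 CPM (SD, n = 4), and EPAS1, which encodes a HIF alpha subunit, rose by 0.96 ± 0.07. A rank-based test did not call this list (adjusted p = 0.362). On the ATF4 and CHOP list, 10 of 46 genes rose and 5 fell (12 and 6 adjusted over the list alone; camera adjusted p = 0.00137, and adjusted p = 0.14 with an estimated correlation), and the rank-based adjusted p was 0.487. Its members with the largest changes, DDIT4 (2.36 ± 0.08) and VEGFA (1.69 ± 0.07), are also known to be induced by low oxygen.

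3 other lists were lower by camera at 4 h with small margins. On the list of DNA double-strand break and crosslink repair, 8 of 34 genes fell and 2 rose (12 and 2 adjusted over the list alone; camera adjusted p = 0.0316, and adjusted p = 0.588 with an estimated correlation), with FANCE at 0.47 ± 0.06. On the unfolded protein list, 9 of 32 fell and 3 rose (9 and 3 adjusted over the list alone; camera adjusted p = 0.0337, and adjusted p = 0.464 with an estimated correlation), with SDF2L1 at −0.73 ± 0.09 and HSPA5 at −0.60 ± 0.06. On the NRF2 list, 5 of 21 fell and 0 rose (5 and 0 adjusted over the list alone; camera adjusted p = 0.0422, and adjusted p = 0.216 with an estimated correlation), with GCLM at −0.59 ± 0.11 and TXNRD1 at −0.36 ± 0.06. Single libraries ended each call. The repair list was at 0.0791 without HCI-2509 4 h replicate 1, 0.0563 without vehicle 4 h replicate 1 and 0.0726 without vehicle 4 h replicate 4. The unfolded protein list was at 0.0741 without HCI-2509 4 h replicate 4, 0.0563 without vehicle 4 h replicate 1 and 0.0764 without vehicle 4 h replicate 4. The NRF2 list was at 0.0791 without HCI-2509 4 h replicate 1, 0.0794 without vehicle 4 h replicate 2 and 0.0726 without vehicle 4 h replicate 4. The histone list was at 0.0544 to 0.0869 without HCI-2509 4 h replicate 3 or 4 or without vehicle 4 h replicate 2, 3 or 4.

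In all, 3872 of 16833 tested genes (23.0%) changed at 4 h, 1991 up and 1881 down. The balance turned to 1849 up and 2063 down with total-count scaling, and to 2318 up and 2952 down with the GC and length correction. A change of at least 2-fold was called for 129 genes, of which 120 rose and 9 fell. The authors' deposited table gave 3492 genes past the same threshold, of which 3452 were shared, and 69 genes changed at least 2-fold by its fold changes. Of 31 lists, 14 passed camera at 4 h and 4 passed with an estimated correlation.

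The lists that did not pass camera at 4 h included the one closest to the question of the series. On the p53 target list, 7 of 51 genes rose and 14 fell (8 and 15 adjusted over the list alone; camera adjusted p = 0.156). BBC3, a pro-apoptotic BCL2 family gene, rose by 0.63 ± 0.14, and the kinase gene PLK2 fell by 0.80 ± 0.15 on the log2 scale. ACER2 at 4 h was at −0.72 ± 0.20, and leaving out HCI-2509 4 h replicate 2 ended its call (−0.59, adjusted p = 0.0524). On the list of genes induced by MYC and MYCN, 5 of 39 rose and 12 fell (6 and 12 adjusted over the list alone; camera adjusted p = 0.639), and LDHA, lactate dehydrogenase A, rose by 1.36 ± 0.04. The mitochondrially encoded list had 1 of 15 genes up and 0 down (1 and 0 adjusted over the list alone; camera adjusted p = 0.056). It passed at 0.0211 without HCI-2509 4 h replicate 1, 0.00567 without HCI-2509 4 h replicate 2, 0.013 without vehicle 4 h replicate 2 and 0.00179 without vehicle 4 h replicate 4. Of 48 cytosolic ribosomal protein genes, 0 rose and 0 fell by edgeR at 4 h (0 and 0 adjusted over the list alone). The remaining lists are given as genes up and down of those tested, then as adjusted over the list alone. They were immediate early genes (8 and 2 of 20, then 10 and 3), BCL2 family and caspases (5 and 5 of 21, then 7 and 7), lysosome and autophagy (6 and 2 of 34, then 6 and 2), adrenergic core regulators (6 and 5 of 23, then 6 and 7) and mesenchymal markers (5 and 4 of 21, then 5 and 5). Further lists were the sympathetic phenotype (2 and 5 of 24, then 2 and 5), REST-repressed genes (2 and 3 of 23, then 2 and 3), genes repressed by MYCN and LSD1 (2 and 3 of 8, then 2 and 3), metallothioneins (0 and 1 of 4, then 0 and 1) and interferon response (0 and 2 of 8, then 0 and 2). Markers of other cell types were scarcely measured, with 1 up and 1 down of 7 fibroblast genes (1 and 2 adjusted over the list alone), 0 and 0 of 3 epithelial genes (then 0 and 0) and 0 and 0 of 3 Schwann and glial genes (then 1 and 1). Median, mean and test differed in sign at 4 h for the MYC, BCL2, interferon, adrenergic, fibroblast, epithelial and Schwann lists.

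The second comparison asked which transcripts had changed after 24 h. Of the 6 largest rises that were named, CA9 was on the hypoxia and HIF list, and the other 5 were not. Here too, absence from the list does not place a gene outside the response to low oxygen. CA9 (carbonic anhydrase 9) went from 3 to 6 counts per vehicle library to 354 to 496 counts per HCI-2509 library, a log2 fold change of 6.89 ± 0.24 (SE, n = 4). NXPH4 went from 1.39 ± 1.02 to 73.3 ± 11.2 CPM and NDUFA4L2, a mitochondrial protein gene, from 2.58 ± 1.47 to 110.1 ± 14.2 CPM (SD, n = 4). KIRREL had 1 count in all vehicle libraries and 127 in all HCI-2509 libraries, a ratio of 140.0 with a 95% exact interval of 24.6 to 5560.0 that covers counting error only, and it was not analysed at 4 h. SMIM3 and AC010441.1 both had a log2 fold change of 5.29 ± 0.14, but their counts were identical and their models overlap, so which gene the reads came from is uncertain. On the hypoxia and HIF list, 33 of 35 genes rose and 1 fell (33 and 1 adjusted over the list alone), with a median of 1.11 and a camera adjusted p of 9.32e-29. The adjusted p was 0.118 with an estimated correlation. PFKFB4 rose 16.4-fold, P4HA1 13.5-fold and FAM162A, a mitochondrial gene, 6.84-fold.

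**Figure D1:**
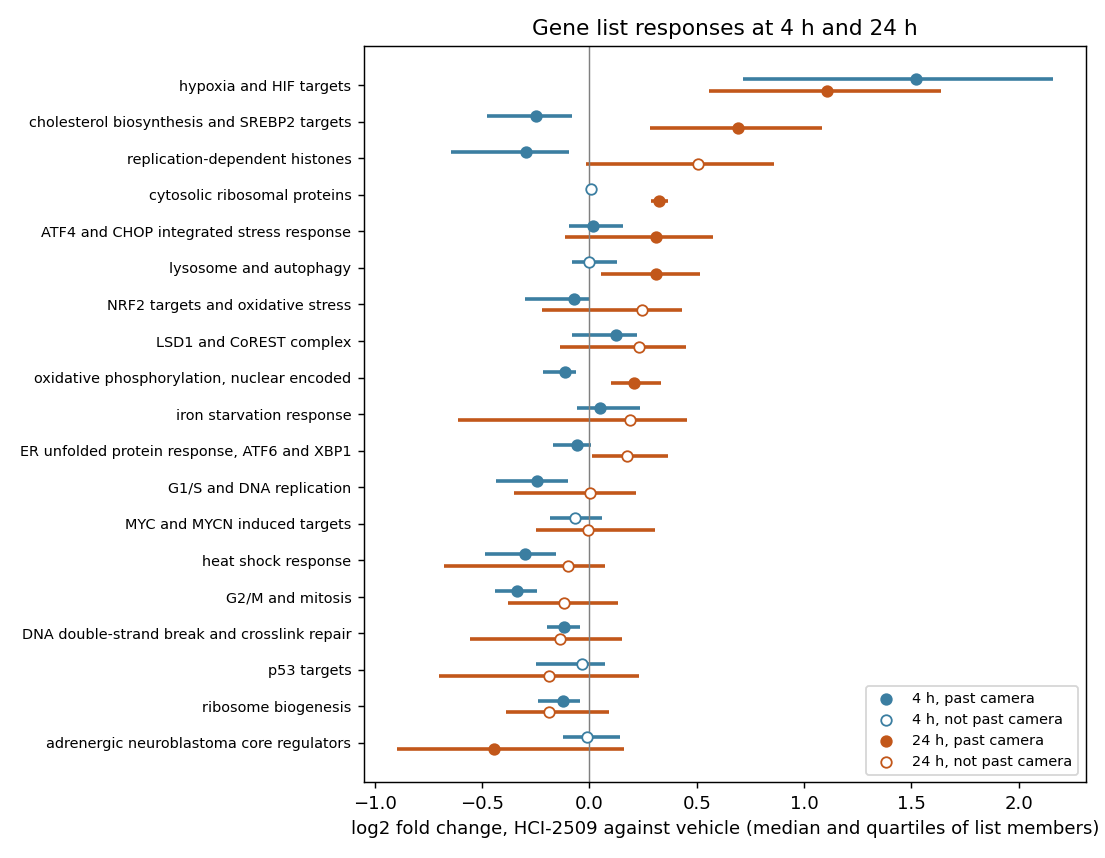
Median and quartiles of the log2 fold change (horizontal axis, HCI-2509 against vehicle) over the tested members of each gene list at 4 h and 24 h, with filled points for lists past camera and open points for the others. The hypoxia and HIF list has medians of 1.52 and 1.11, and the cholesterol list lies below 0 at 4 h and above 0 at 24 h.

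The largest falls at 24 h were in genes of several kinds. MAT2A, which makes the methyl donor S-adenosylmethionine, went from 159.4 ± 12.1 to 13.2 ± 0.969 CPM, and B3GALT2, a galactosyltransferase gene, from 10.5 ± 0.478 to 0.788 ± 0.305 CPM (SD, n = 4). PAX7, a developmental transcription factor, had 35 to 64 counts per vehicle library and 1 to 3 per HCI-2509 library, a log2 fold change of −4.31 ± 0.34. The mitochondrial tRNA MT-TF fell by 3.75 ± 0.35, RP11-710C12.1 by 3.50 ± 0.12 and C1orf173 by 3.48 ± 0.31 on the log2 scale. MT-TF and C1orf173 fell to 0.146 and 0.198 CPM, so the size of their falls is imprecise. Since the libraries were poly(A) selected, the reads of MT-TF may not measure the mature tRNA.

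Sterol genes were higher at 24 h. On the cholesterol and SREBP2 list, 23 of 25 genes rose and 2 fell (23 and 2 adjusted over the list alone; camera adjusted p = 2.72e-13, and adjusted p = 0.028 with an estimated correlation). MSMO1 went from 73.4 ± 4.88 to 235.1 ± 17.4 CPM (SD, n = 4), and MVK, DHCR7 and MVD, all enzymes of the pathway, rose by 1.60 ± 0.06, 1.59 ± 0.05 and 1.40 ± 0.07. Of the adrenergic neuroblastoma core regulators, 15 of 23 fell and 7 rose (15 and 7 adjusted over the list alone; camera adjusted p = 9.48e-05, and adjusted p = 0.0428 with an estimated correlation). Of its members, the transcription factor genes SOX11 and KLF13 fell by 1.24 ± 0.05 and 1.12 ± 0.05 on the log2 scale. On the ATF4 and CHOP list, 27 of 46 genes rose and 10 fell (27 and 10 adjusted over the list alone; camera adjusted p = 0.00124, and adjusted p = 0.191 with an estimated correlation), with ATF5 at 1.41 ± 0.08 and SHMT2, a mitochondrial serine enzyme, at 1.28 ± 0.05. On the lysosome and autophagy list, 22 of 34 rose and 6 fell (22 and 6 adjusted over the list alone; camera adjusted p = 0.015, and adjusted p = 0.275 with an estimated correlation). The lysosomal regulators TFEB and TFE3 rose by 1.37 ± 0.10 and 1.20 ± 0.08.

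Genes of translation and respiration had small rises at 24 h. All 48 tested cytosolic ribosomal protein genes rose (48 adjusted over the list alone), with a median of 0.32, and 35 did with total-count scaling and 44 with the GC and length correction and the block. The camera adjusted p was 9.48e-05, the adjusted p was 0.695 with an estimated correlation, and 19 of the 35 splits of the 8 libraries gave a camera p as small (2 of the 8 splits that part all pairs, with the block). RPS27 rose by 0.70 ± 0.12 and RPS12 by 0.48 ± 0.06. On the nuclear-encoded oxidative phosphorylation list, 44 of 59 rose and 5 fell (44 and 5 adjusted over the list alone; camera adjusted p = 0.0116, and adjusted p = 0.695 with an estimated correlation), and 15 of the 35 splits gave a camera p as small (4 of the 8 with the block). With total-count scaling 23 rose and 9 fell, and with the GC and length correction and the block 40 and 7. ATP5D, an ATP synthase subunit, rose by 0.63 ± 0.08, and an entry for SDHD (ENSG00000255292) by 0.64 ± 0.19, which is uncertain because 2 entries carry that symbol. With total-count scaling the oxidative phosphorylation list was at an adjusted p of 0.0677 and with the GC and length correction at 0.0607.

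In all, 11907 of 16822 tested genes (70.8%) changed at 24 h, 5938 up and 5969 down, and 2286 changed at least 2-fold, of which 653 rose and 1633 fell. The share of rises among the changed genes was 49.9%, and with total-count scaling it was 36.4%, since that scaling moved the median of all genes by −0.149 log2. The authors' deposited table gave 11637 genes past the threshold, of which 11212 were shared. Of 29 lists, 7 passed camera at 24 h and 2 passed with an estimated correlation. Of the 35 splits of the 8 libraries, 9 gave as many lists as the real one, so the number of lists is not beyond what other splits gave.

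The lists that did not pass camera at 24 h included p53 targets, with 14 of 51 genes up and 28 down (14 and 28 adjusted over the list alone; camera adjusted p = 0.263). TP53INP1, a stress-induced gene, went from 12.7 ± 0.592 to 1.77 ± 0.218 CPM, CES2 fell by 1.36 ± 0.08, and PGF, a growth factor gene, rose by 1.40 ± 0.07. ACER2 fell by 1.65 ± 0.24 on the log2 scale. On the LSD1 and CoREST list, 12 of 21 rose and 5 fell (14 and 5 adjusted over the list alone; camera adjusted p = 0.12). PHF21A, a CoREST complex gene, rose by 0.83 ± 0.04, and INSM1, a neuroendocrine transcription factor, went from 130.4 ± 9.74 to 46.1 ± 2.80 CPM. The list of genes induced by MYC and MYCN had 16 of 39 up and 13 down (16 and 13 adjusted over the list alone; camera adjusted p = 0.128), and it was higher with the replicate block (adjusted p = 0.0392) but not with the block and the GC and length correction (0.313, 18 up and 18 down) or with an estimated correlation (0.733). With total-count scaling 11 of its genes rose and 20 fell. G2/M and mitosis had 15 of 61 up and 30 down (15 and 30 adjusted over the list alone; camera adjusted p = 0.154), and it was lower with the block (adjusted p = 0.0392) but not with the block and the correction (0.224, 23 up and 25 down) or with an estimated correlation (0.836). With total-count scaling 4 rose and 40 fell. CKS2 at 24 h was at 0.10 ± 0.06 without the block, and with the block it was called (adjusted p = 0.0379). The other lists are again given as genes up and down of those tested, then adjusted over the list alone. They were G1/S (17 and 20 of 49, then 17 and 20), ribosome biogenesis (9 and 25 of 38, then 9 and 25), histones (14 and 4 of 29, then 13 and 4), double-strand break repair (9 and 16 of 34, then 9 and 16), unfolded protein response (19 and 6 of 32, then 19 and 6), heat shock (5 and 9 of 19, then 5 and 9), NRF2 (11 and 7 of 21, then 11 and 7) and iron starvation (7 and 4 of 12, then 7 and 4). Further lists were mitochondrially encoded genes (7 and 4 of 15, then 7 and 4), metallothioneins (3 and 2 of 5, then 3 and 2), BCL2 family (9 and 10 of 21, then 9 and 10), genes repressed by MYCN and LSD1 (3 and 3 of 8, then 3 and 3), immediate early genes (9 and 8 of 18, then 9 and 8), the sympathetic phenotype (12 and 8 of 25, then 12 and 8), REST-repressed genes (7 and 13 of 23, then 7 and 13), mesenchymal markers (8 and 11 of 24, then 8 and 11), interferon response (0 and 1 of 8, then 0 and 0), fibroblast markers (1 and 4 of 7, then 1 and 4), epithelial markers (1 and 1 of 2, then 1 and 1) and Schwann markers (0 and 2 of 2, then 0 and 2). The last 2 lists had too few members for camera. The balance turned to 16 up and 11 down for double-strand break repair and to 9 and 8 for mesenchymal markers with the GC and length correction and the block, and to 10 and 13 for the sympathetic phenotype with total-count scaling. That scaling also gave 10 up and 26 down for G1/S, 11 and 8 for the unfolded protein response, 8 and 8 for NRF2, 5 and 5 for iron starvation and 5 and 5 for mitochondrially encoded genes. Histones went to 10 and 7 with it, and the ATF4 and CHOP list, which passed camera, went to 22 and 14. Median, mean and test differed in sign at 24 h for the MYC, MYCN and LSD1 repressed, BCL2, G1/S and mesenchymal lists.

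Genes tied to the inhibitor and to the question of the series were read at both times. KDM1A (ENSG00000004487), which encodes the drug target, was at 0.08 ± 0.04 at 4 h (log2 ± SE, adjusted p = 0.22) and rose by 0.29 ± 0.04 at 24 h. MDM2 (ENSG00000135679), a member of the p53 target list, fell by 0.26 ± 0.06 at 4 h and went from 521.1 ± 39.0 to 224.5 ± 17.0 CPM at 24 h (SD, n = 4). MYCN (ENSG00000134323), the oncogene, fell by 0.30 ± 0.04 at 4 h and by 0.70 ± 0.04 at 24 h on the log2 scale. CDKN1A (ENSG00000124762), which encodes the cell cycle inhibitor p21, went from 46.6 ± 1.75 to 29.1 ± 2.79 CPM at 4 h. CDKN1A at 24 h was at −0.14 ± 0.06 (edgeR adjusted p = 0.0447), and DESeq2 gave 0.0853, no filter 0.0753, the authors' deposited adjusted p was 0.0847 and the fit of 16 libraries gave 0.0501. Without HCI-2509 24 h replicates 1, 3 and 4 in turn the adjusted p was 0.0528, 0.0886 and 0.095, and without vehicle 24 h replicates 2 and 4 it was 0.0985 and 0.138.

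**Figure D2:**
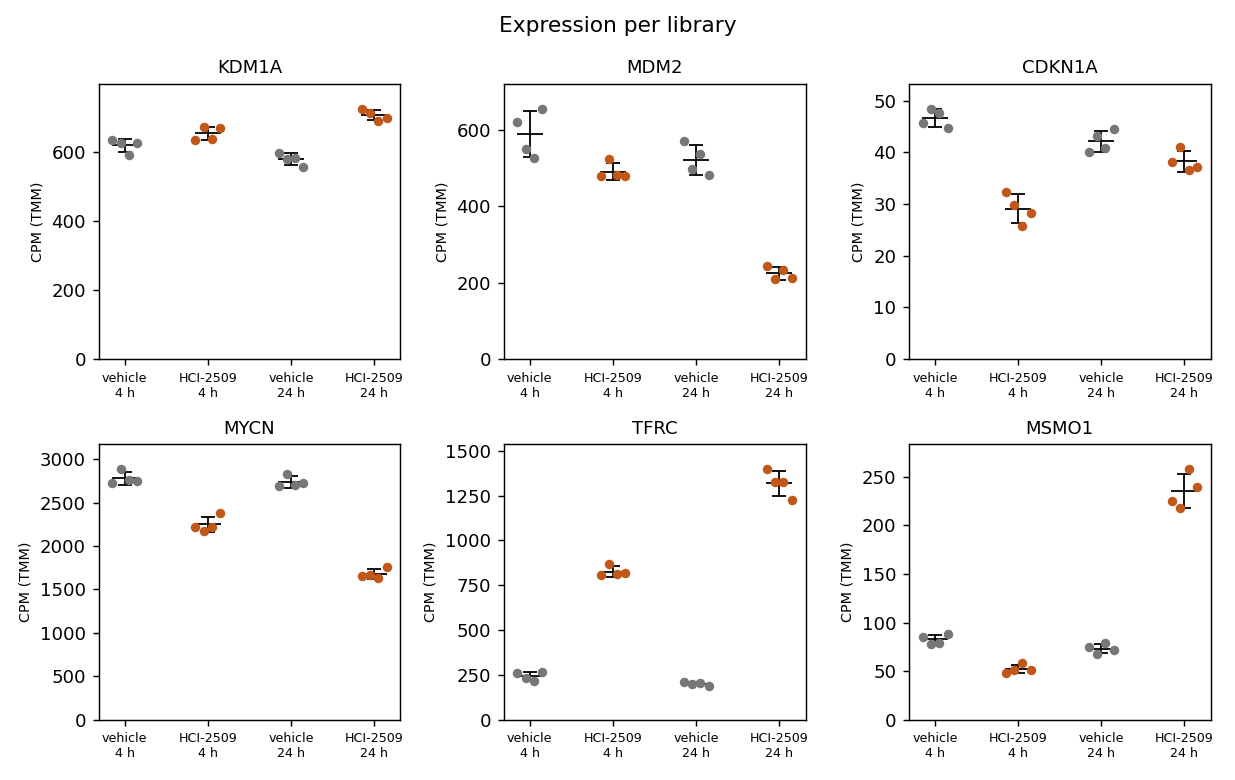
CPM (vertical axis, from 0) of KDM1A, MDM2, CDKN1A, MYCN, TFRC and MSMO1 in each library, with points for libraries and bars for mean ± SD (n = 4). The HCI-2509 libraries at 24 h average 224.5 CPM for MDM2 against 521.1 in vehicle.

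The third comparison asked whether the response differed between the times. The sterol genes had the smallest p among the lists (camera adjusted p = 5.02e-32, and adjusted p = 1.43e-05 with an estimated correlation), with a median difference of 0.924 log2 between the 24 h and the 4 h effect. The median difference was larger for histones (1.171, camera adjusted p = 0.016, and adjusted p = 0.671 with an estimated correlation). MSMO1 fell at 4 h and rose at 24 h, a difference of 2.34 ± 0.09 (SE), and HMGCS1, INSIG1 and IDI1 differed by 1.76 ± 0.10, 1.57 ± 0.07 and 1.66 ± 0.11. The adrenergic list moved down between the times (camera adjusted p = 1.6e-05, and adjusted p = 0.0431 with an estimated correlation). BHLHE40, STC1, SLC2A1 and VEGFA had smaller rises at 24 h than at 4 h, by −1.89 ± 0.28, −1.80 ± 0.21, −1.23 ± 0.09 and −1.33 ± 0.10, whereas TFRC rose further (0.94 ± 0.08). The unfolded protein gene HSPA5 fell at 4 h and rose by 0.52 ± 0.05 at 24 h, and CTD-2636A23.2 likewise rose by 0.80 ± 0.12 at 24 h. The hypoxia list as a whole did not pass (camera adjusted p = 0.117), nor did the p53 list (0.581). In the one fit of all libraries, 9704 of 17408 genes differed, 4631 upward and 5073 downward, of which 2053 differed by at least 2-fold, 344 upward and 1709 downward.

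Of 16560 genes tested at both times, 1399 rose at both against 700.4 for independent lists, and 1203 fell at both against 675.4. Opposite calls were fewer than independent lists would give, with 281 up then down against 713.2 and 271 down then up against 663.3. Across genes, which are not independent replicates, the fold changes at the 2 times had a Pearson r of 0.431 and a Spearman rho of 0.409.

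**Figure D3:**
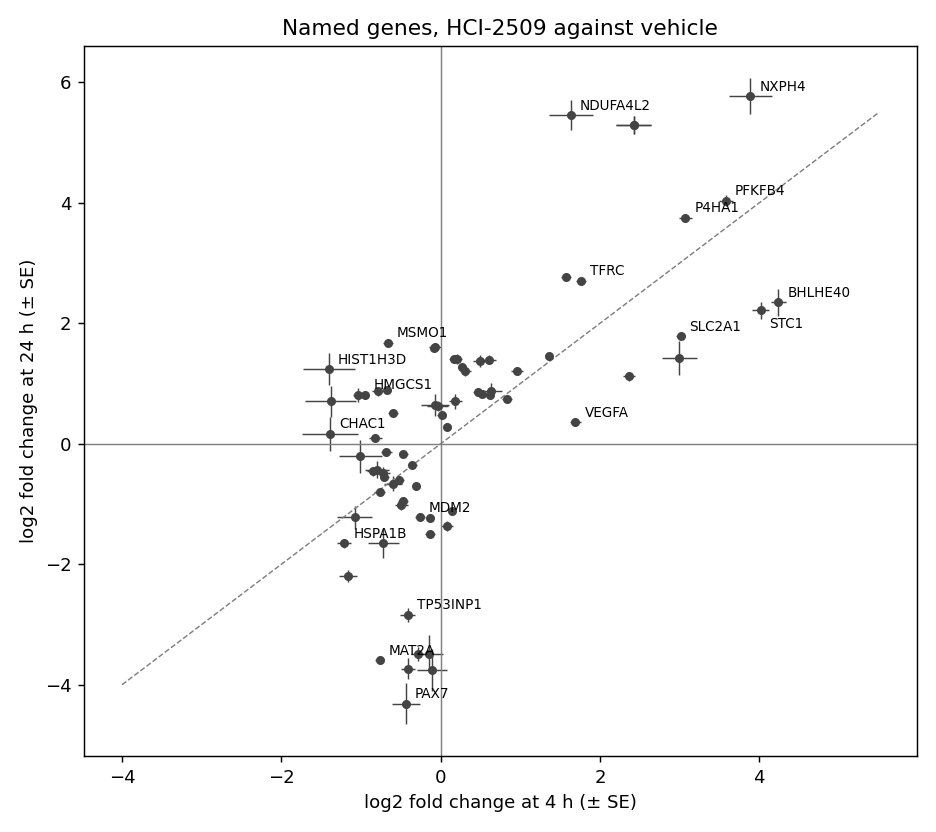
Log2 fold change at 4 h (horizontal axis) and 24 h (vertical axis) of the named genes tested at both times, with bars of ± SE and a dashed line of equal change. NXPH4 lies at 3.89 and 5.77, BHLHE40 at 4.24 and 2.35, and MAT2A at −0.77 and −3.59.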

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

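The tests of GC content, transcript length and scaling, the exact test over splits for the iron list, and the splits of pairs with the block, were chosen only after the results were seen, while the other splits and the camera test of the iron list were written before.

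A first group of values stood apart from the other 3 libraries of their group, with a gap to the nearest library that exceeded the critical share of the range (Dixon's ratio). This met 22 of 318 groups of 4, and chance alone gives about 1 in 20. At 4 h under HCI-2509 these were BHLHE40 (79.06 CPM) and HSPA1B (28.19) in replicate 4, SNORD3A (1.318), MT-TF (1.245) and HIST1H3D (0.8054) in replicate 1, and MDM2 (523.9) and ATP5D (89.39) in replicate 2. The number of detected genes in HCI-2509 4 h replicate 1 was 18358. In vehicle at 4 h they were NDUFA4L2 (2.719 CPM) and MAT2A (169.1) in replicate 3, MT-TF (2.12) in replicate 1 and PCNA (305.2) in replicate 2. In vehicle at 24 h they were PFKFB4 (4.337) and ACER2 (1.41) in replicate 4, KIRREL (0.05649) in replicate 1, ATF5 (14.3) in replicate 3, and NDUFA4L2 (4.755), SMIM3 (1.324) and AC010441.1 (1.324) in replicate 2. Under HCI-2509 at 24 h they were CKS2 (125.3), RPS27 (46.42) and KLF13 (102.1), each in replicate 2.

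A second group differed between the times by the interaction test of edgeR (adjusted p under 0.05), which 63 of 76 named genes did. The values are log2 differences of the 24 h effect from the 4 h effect. Those below −2 were PAX7 (−3.88), MT-TF (−3.65), C1orf173 (−3.34), B3GALT2 (−3.32), RP11-710C12.1 (−3.21), MAT2A (−2.83) and TP53INP1 (−2.43). Those from −2 to −1 were BHLHE40 (−1.89), STC1 (−1.80), ADM (−1.57), CES2 (−1.44), INSM1 (−1.36), VEGFA (−1.33), KLF13 (−1.26), DDIT4 (−1.24), SLC2A1 (−1.23), SOX11 (−1.10) and HSPA2 (−1.03). Smaller negative differences were MDM2 (−0.96), ACER2 (−0.93), UTP15 (−0.53), RRS1 (−0.49), HSPA1B (−0.44) and MYCN (−0.40). Positive differences below 0.6 were RCOR3 (0.19), KDM1A (0.20), EPAS1 (0.24), NDUFS6 (0.29), PHF21A (0.31), FANCE (0.39), CENPA (0.39), PFKFB4 (0.45), RPS12 (0.47), RPS27 (0.51) and CDKN1A (0.54). Those from 0.6 to 1.2 were ATP5D (0.66), P4HA1 (0.68), the SDHD entry ENSG00000255292 (0.71), PGF (0.79), TFEB (0.88), TFE3 (0.89), CKS2 (0.91), TFRC (0.94), SHMT2 (1), HSPA5 (1.11), FAM162A (1.19) and ATF5 (1.20). The remaining ones were MVD (1.23), CHAC1 (1.56), INSIG1 (1.57), IDI1 (1.66), DHCR7 (1.66), MVK (1.68), HMGCS1 (1.76), CTD-2636A23.2 (1.83), NXPH4 (1.89), HIST1H1B (2.08), MSMO1 (2.34), HIST1H3D (2.64), SMIM3 (2.87), AC010441.1 (2.87), NDUFA4L2 (3.83) and CA9 (4.88).

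A further group was the 10 lists whose camera test of the difference between times passed. Their adjusted p-values were 5.02e-32 for cholesterol, 1.42e-08 for oxidative phosphorylation, 5.42e-06 for ribosomal proteins, 1.6e-05 for adrenergic regulators, 0.00203 for G1/S, 0.00509 for G2/M, 0.00616 for the unfolded protein response, 0.00775 for lysosome, 0.016 for histones and 0.0168 for ATF4 and CHOP. With an estimated correlation, those of cholesterol and of adrenergic regulators passed.

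Other splits of the libraries tested whether chance could give as much. At 4 h the real split gave 3872 genes against at most 18 in the others, and 129 genes at 2-fold against 7. It gave 14 lists against 12. A share of 1 of 35 splits is the smallest that this test can give. For each of these counts only the real split gave as many. This does not hold for each list at 4 h, since the camera p was as small in 17 of 35 splits for histones, 12 for repair, 6 each for the unfolded protein and NRF2 lists, 3 each for G2/M, G1/S, ribosome biogenesis and oxidative phosphorylation, and 2 for heat shock. At 24 h the real split gave 11907 genes and 2286 genes at 2-fold against 0 in the others by edgeR (1 of 35). For the 7 lists 9 of 35 splits gave as many (highest other 9), so chance cannot be excluded for that count. Taken one at a time, the camera p at 24 h was as small only in the real split (1 of 35) for the hypoxia, cholesterol, adrenergic and ATF4 lists, and in 6 of 35 for lysosome (3 of the 8 that part all pairs, with the block). The difference between times gave 9704 genes, and of 100 splits that included the real one, only the real one gave as many. The highest other draw gave 9347, and it kept the real groups at 24 h and 6 of 8 labels at 4 h. The draws reassigned treatment within each time and so broke up the effect itself. They could not test whether that effect differed between the times. Since the numbers may pair the libraries at 24 h, the 7 other splits that part all pairs were compared. They gave 0 genes and at most 7 lists. With only 8 splits that part all pairs, the smallest possible share is 1 of 8. The splits thus cannot exclude chance for the gene counts at 24 h, although no other split gave any gene.

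The hypoxia and HIF list was higher at both times. The list lost its call at 24 h with an estimated correlation (adjusted p = 0.118). It kept it with a median of 1.13 (lower quartile 0.775) after the correction for GC content and transcript length, which argues against these as the whole cause. The call was also kept with total-count scaling, but the lead over the median of other genes was 1.095 with either scaling, so the call could not test scaling. The median with total-count scaling was 0.956 (lower quartile 0.411), so a rise remained under that scaling too. Lowered cellular iron, which stabilizes HIF, may be a cause. Without TFRC and without members of the hypoxia list, the iron list had 10 tested members at 4 h, of which 2 rose and 1 fell. As a set these 10 members had p = 0.255 by camera, and the exact two-sided test over the 35 splits gave p = 0.171 (6 splits as small). Lowered iron thus cannot be told apart from other causes with so few members. Treatment with HCI-2509 is the difference that the design names, and through which target it acted was not tested.

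The ribosomal protein and oxidative phosphorylation lists were higher at 24 h, when fold changes also followed transcript length (rho −0.235 across genes) and GC content (rho 0.259), and both calls were lost with an estimated correlation (adjusted p = 0.695 for each). For ribosomal proteins the correction left a median of 0.245 (lower quartile 0.178) with the call kept, which argues against GC content and length as the whole cause. Total-count scaling left one of 0.173 (lower quartile 0.137), also with the call kept. The lead over the median of other genes was 0.313 with TMM and 0.312 with that scaling, so the kept call could not test scaling. The lower quartile above 0 shows only that a rise remained under that scaling. For oxidative phosphorylation the correction took the median from 0.206 ± 0.036 to 0.159 ± 0.040 (SE over list members). It took the lead over the median of other genes from 0.197 to 0.129 and ended the call (adjusted p = 0.0607). With part of the rise left, GC content and length cannot be told apart from a treatment effect. With total-count scaling the median of that list was 0.057 ± 0.036 (adjusted p = 0.0677) but its lead was 0.196, since other genes moved alike, so why the call ended was not tested and scaling cannot be told apart from a rise in the level of these genes. The camera p was as small as the real one in 19 and 15 of 35 splits without the block and in 2 and 4 of the 8 splits that part all pairs with the block, so chance was not excluded at the level of the list.

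The p53 target list was not higher at 24 h, with 14 genes up and 28 down. It did not pass camera, which compares a list with other genes (adjusted p = 0.263). The fry test, which makes no such comparison, called the p53 list lower at 4 h (adjusted p = 0.00865) and at 24 h (adjusted p = 1.05e-05). At 24 h fry passed 23 of 29 lists. After the correction for GC content and length the median of the p53 list at 24 h was −0.111. The standard error of that median over list members was 0.122, so a bias hiding a rise can neither be excluded nor shown. Some members of the list were not analysed here, and a biological cause was not tested.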

How the results depend on the processing

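Total-count scaling and the GC and length correction were chosen after seeing the data, and all other alternatives were planned. Of named genes and list members at a time point, 324 of 386 kept direction and side of the threshold under every alternative run, and of lists at a time point 23 of 60 did. Leaving out 1 library at a time left 2908 to 4353 genes at 4 h, 11493 to 11767 at 24 h, 135 to 168 and 2292 to 2547 genes at 2-fold, 9239 to 9749 genes that differed between times, 11 to 15 lists at 4 h and 7 to 7 lists at 24 h. An adjusted p under 0.01 left 2172 genes at 4 h, since it is stricter, and the authors' deposited table gave 69 genes at 2-fold at 4 h, where the cause was not tested. With an estimated correlation 4 lists passed at 4 h and 2 at 24 h. The estimate was far above the preset 0.01 for some lists that lost their call, such as G2/M at 4 h (0.62) and ribosomal proteins at 24 h (0.622). The NRF2 list lost its call at 4 h with an estimate of 0.012. For iron starvation at 4 h the estimate was −0.017, below the preset, yet the camera p rose from 3.92e-05 to 0.00491. For adrenergic regulators at 24 h the estimate was −0.009, and the camera p rose from 1.31e-05 to 0.00295. The estimate is thus not the whole cause of the higher p-values with this setting, and the rest was not tested. The fry test, which does not compare a list with other genes, passed 23 lists at 24 h. DESeq2 gave 3603 genes at 4 h and 11613 at 24 h, and among genes whose response differs between 24 h and 4 h it gave 9366. With the replicate block, 2963 genes passed at 4 h, 12547 passed at 24 h and 9788 differed between times. At 4 h same-numbered libraries had correlations of −0.091, −0.467, 0.086 and −0.250 and were not taken as paired. At 24 h the block changed no list call other than those of G2/M and of genes induced by MYC and MYCN, and with the GC and length correction as well neither passed (0.224 and 0.313). At 4 h it also called the mitochondrially encoded list (adjusted p = 0.0129), as did the GC and length correction (0.0135) and the rank-based test (0.00278), which ended the call of the unfolded protein list (0.0575). The GC and length correction gave 5270 genes at 4 h and, with the replicate block, 11940 at 24 h. It ended the 4 h calls of the repair and NRF2 lists (both 0.0585) and of histones (0.446, and 0.0518 with total-count scaling), and at 24 h with the block it called the LSD1 and CoREST (0.0178), iron starvation (0.0134), REST-repressed (0.0274) and ribosome biogenesis lists (0.0349, and 0.0335 with total-count scaling). The direction reversed for TXN at 24 h with total-count scaling (−0.1142), and with the correction for SLC39A10 at 24 h (0.0867 without and 0.0856 with the block) and NDUFB7 at 24 h (−0.3031 and −0.3044), and the cause was not tested. Pseudocounts, quantile scaling and expression floors did not apply to counts, and the authors' deposited table holds no test of the difference between times. Low counts limit the precision of MIR210HG, KIRREL, CA9 and PAX7. They also limit that of MT-TF (0.146 CPM) and C1orf173 (0.198 CPM) under HCI-2509 at 24 h. The same holds for HIST1H3D (0.426 CPM) and HIST1H1B (0.443 CPM) under HCI-2509 at 4 h.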

Other observations

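All lists and genes in the next 2 paragraphs were chosen after values had been seen, so their tests are descriptive.

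Glycolytic genes rose at both times. Of 16 tested, 13 rose and 0 fell at 4 h (median 0.535, adjusted p = 0.000206 with an estimated correlation), and 16 rose at 24 h (median 1.42, adjusted p = 0.00114 with an estimated correlation). Leaving out members of the hypoxia list left 15 of the 16 genes, of which 12 rose at 4 h and 15 at 24 h. With so few genes left out, this scarcely tests a rise apart from the hypoxia response. HK2, a hexokinase, rose by 2.65 ± 0.05 (log2 ± SE) at 4 h and 1.26 ± 0.07 at 24 h, while ALDOC, an aldolase, rose by 1.12 ± 0.10 and 2.95 ± 0.06, and PGK1, phosphoglycerate kinase, by 0.65 ± 0.05 and 1.85 ± 0.04.

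Genes of 2-oxoglutarate oxygenases, enzymes that need oxygen and iron, rose at 4 h in 19 of 34 cases and fell in 0 (adjusted p = 0.000277 with an estimated correlation), and without members of the hypoxia list in 11 of 25 (adjusted p = 0.0164). At 24 h 20 rose and 10 fell (adjusted p = 0.0632 with an estimated correlation), and without members of the hypoxia list 12 of 25 rose and 10 fell (median 0.019, camera adjusted p = 0.154). The histone demethylase genes KDM3A and KDM4B rose by 2.16 ± 0.05 and 0.70 ± 0.05 at 4 h and by 2.37 ± 0.05 and 0.89 ± 0.05 at 24 h. TET3 rose by 0.31 ± 0.06 at 4 h and fell by 1.05 ± 0.07 at 24 h, and TET2 rose by 0.43 ± 0.07 and then fell by 0.65 ± 0.07 on the log2 scale. Of 17 genes of serine and one-carbon metabolism, 3 rose and 5 fell at 4 h (camera adjusted p = 0.0815), and 6 rose and 8 fell at 24 h (0.384).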
